A study of Sus scrofa with 6 samples.

How the data were processed

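Aortic valve leaflets from adult female pigs, stripped of endothelium with collagenase, were held in a bioreactor under cyclic pressure for 24 h at 1 Hz, per the labels' protocols. The pressure ran from 0 to 80 mmHg in the normotensive group and from 0 to 120 mmHg in the hypertensive group, with 3 samples of leaflets in each. Per the labels, 70 ng of total RNA per sample was amplified by repeated in vitro transcription, and 10 µg of biotin-labelled cRNA was hybridised to the Affymetrix Porcine Genome Array. The labels call the samples biological replicates and do not settle whether a sample was a single leaflet or whether samples came from separate animals, so p-values measure the spread between these samples, which may share a donor.

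The deposited values are signal intensities on a linear scale, 1 per probe set and array. Per the submitters' processing notes, the authors used GCOS and MAS5; versions are not given in the sources used here. The 2% trimmed mean of the deposited intensities lay between 500.11 and 500.131 on the 6 arrays, so each array had been scaled to a common level, and medians ran from 88.1 to 99.2. Scaling of this kind removes any difference in total RNA per array, and a change that moved most transcripts the same way would not be seen. Detection calls were not used here, and the number of arrays limits the precision.

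The table held 24123 probe sets, of which 124 control probe sets were left out of the tests. Gene symbols came from the platform annotation. Of the other 23999 probe sets, 10069 had 1 gene symbol, 198 had several and 13732 had none, and no gene was named from a probe set with several. Intensities were taken to log2 with no pseudocount and no further normalization. Probe sets whose mean log2 intensity was at or above the 40th percentile were kept, which corresponds to a signal of 48.5. This left 14399 probe sets, of which 6891 had 1 symbol, and 5271 genes after the brightest probe set was taken for each gene.

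Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend, 2-sided), adjusted by the Benjamini-Hochberg method over all kept probe sets at a threshold of 0.05. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists with at least 5 measured genes, with fry beside it. The 39 lists, the filter, the tests, the alternatives and the rule for naming genes were chosen before the data were examined. An exact permutation test of 3 arrays against 3 cannot give a p below 0.1, so none was used for single genes.

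The rule for named genes took, in each direction, up to 12 genes past the threshold with groups that did not overlap, ranked by fold. Where fewer than 12 passed, the places were filled with genes of non-overlapping groups at an unadjusted p under 0.01, ranked by p and said not to have passed. It also took up to 4 genes of smallest p from each list described, and GAPDH and ACTB as controls. IL6, IL1B, TIMP2 and TIMP3 were chosen after their values were seen. A gene below the filter level on all arrays of a group is given a fold against that level, as a lower bound. Of 41 genes named in these ways with further kept probe sets, 27 had all of them in the same direction and 14 did not.

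The tests were checked on simulated data with the intensities and spread of the 14399 kept probe sets and independent noise, in 10 runs of 200 changed probe sets. Of changes of 1 on the log2 scale, 9.70% were recovered; of changes of 2, 70.6%; and of changes of 4, 99.2%. Of all calls, 5.99% were false. A shift of 1 in the interferon list, among 5271 genes, was called by camera in 10 of 10 runs and by fry in 6, and 3 of 350 tests of other lists were called. The simulation held no correlation between genes and no array that stood apart.

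Alternatives were the replicate number as a block, quantile normalization, a median shift, no filter, a filter at the 60th percentile, pseudocounts of 16 and 64, other variance models, array weights, each array left out in turn, and for lists an estimated correlation, fry and the mean of all kept probe sets of a gene.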

Results

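Transcript levels were measured on 6 arrays, 3 from aortic valve leaflets under normotensive cyclic pressure and 3 from leaflets under hypertensive cyclic pressure. The comparison asks how 24 h of raised pressure changes expression in the leaflet once the endothelium is stripped. Some markers of other cells than interstitial cells still had signal under normotensive pressure, with macrophage CD163 at 1636 and endothelial ERG at 1504. Further markers were much lower, with endothelial ENG, SELP and TEK at 125, 128 and 63.6. The leukocyte markers PTPRC, CORO1A and CD14 were at 77.6, 71.4 and 40.7. These signals do not show how much of either cell type remained. Changes are therefore not assigned to a cell type. Values are MAS5 signals, and differences are given on the log2 scale as hypertensive minus normotensive, with the standard error of the fit and 3 arrays per group. Correlations across kept probe sets were 0.952 to 0.978 between normotensive arrays. Hypertensive replicate 2 had a mean correlation of 0.950 with the normotensive arrays, against 0.895 for replicate 3 and 0.817 for replicate 1.

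**Figure D1:**
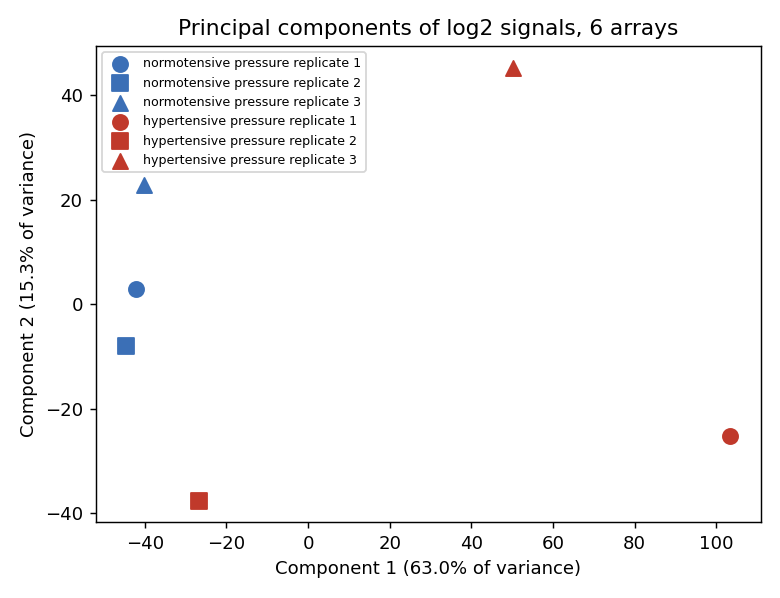
Principal components of the log2 signals of 14399 kept probe sets, with component 1 on the horizontal axis and component 2 on the vertical axis in log2 units; each point is 1 array. Hypertensive replicates 1 and 3 lie at 103.4 and 50.3 on component 1, while hypertensive replicate 2 lies at -26.7, near the normotensive arrays at -44.6 to -40.2.

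By camera at a preset correlation, the lists of interferon response genes and of inflammatory cytokines rose at hypertensive pressure and that of the cell cycle fell. None of these 3 calls held with an estimated correlation (adjusted p = 0.679 for each). None held with fry either (adjusted p = 0.297 for interferon and 0.146 for each of the cytokine and cell cycle lists). No single gene passed the genome-wide threshold. The signal of NFKBIA, the inhibitor that NF-kB induces against itself, was 4.54 times the normotensive level, with a log2 difference of 2.18 (SE 0.28). That of CXCL8, a neutrophil-attracting chemokine, was 6.61 times the normotensive level (log2 2.72, SE 0.36). ACSL1, which activates long-chain fatty acids, was at 13.02 times (log2 3.70, SE 0.46). MMP3, a protease that cleaves matrix proteins, lay below the filter level on every normotensive array and was at least 67.6-fold higher at hypertensive pressure, a limit that was 32.6-fold without hypertensive replicate 1 and 137-fold without hypertensive replicate 2. Among genes with less signal, asporin (ASPN), a small leucine-rich proteoglycan, was at 5021 under normotensive and 1045 under hypertensive pressure. The delta-sarcoglycan gene SGCD was at 2122 and 379. In each of these genes all 3 hypertensive arrays lay on one side of all 3 normotensive arrays, and none passed, with adjusted p between 0.115 and 0.164.

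By limma, 0 of 14399 probe sets passed an adjusted p of 0.05, and 2436 had an unadjusted p under 0.05, of which 1064 were higher and 1372 lower. Chance alone gives 720 such probe sets. The groups did not overlap in 1501 probe sets that were higher and 1733 that were lower, together 22.5% where chance gives 10%. Without hypertensive replicate 2, 3513 probe sets passed, 1500 higher and 2013 lower. With array weights 5639 passed; the weights were 0.195 for hypertensive replicate 2, 0.289 for hypertensive replicate 1, 2.38 for hypertensive replicate 3 and 6.96 for normotensive replicate 1. Without normotensive replicate 2, 1 probe set passed. The fold of 17 of the 74 genes reported moved by over 1.5 times without 1 array, in 12 genes without hypertensive replicate 1, in 13 without replicate 2 and in 4 without replicate 3, and in 0 without a normotensive array. These were MMP3, IL6 and IL1B, and, by at most 2.21 times, MARCH3, UBD, IFIT2, CCL8, RRM2, MMP1, ADAMTS1, ALDOC, ENO2, GPI, SELP, CD163, VEGFA and C5.

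The rule named 12 genes with higher signal and 12 with lower signal, none of them past the threshold. Beside those above, the higher group held TAP1, the peptide transporter of antigen presentation, at 9.76 times the normotensive signal, and UBD, a ubiquitin-like modifier, at 10.3 times. The chemokine CXCL9 was at 6.37 times, the leukocyte adhesion molecule ICAM1 at 4.07 times and arginase (ARG1) at 3.90 times. MARCH3, XAF1 and IL27RA were at 9.21, 4.23 and 2.84 times. The lower group held the complement component C7, at 4679 under normotensive and 1248 under hypertensive pressure, and the secretory GTPase RAB27B, at 407 and 76.0. NDC80 and NEK2, which act in chromosome segregation, were at 265 and 60.8, and at 238 and 67.6. QDPR, SH3BGR, LMCD1, EPDR1 and DIRAS3 had log2 differences of -1.37, -1.89, -1.94, -1.46 and -1.83. C1QTNF12 lay below the filter level on every hypertensive array and was at least 6.36-fold lower. Adjusted p for the 24 genes lay between 0.115 and 0.168.

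**Figure D2:**
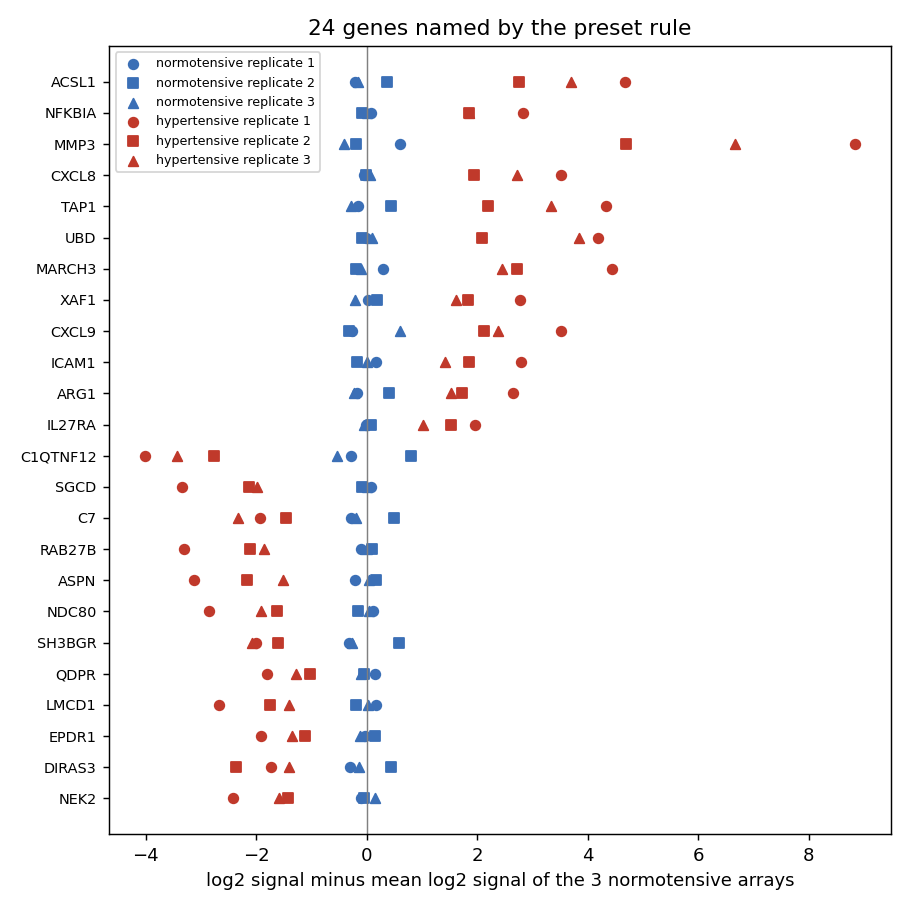
Signals of the 24 genes named by the rule, as log2 signal minus the mean log2 signal of the 3 normotensive arrays, with 1 row per gene and 1 point per array. In each gene the 3 hypertensive arrays lie on one side of the 3 normotensive arrays.

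The interferon response list rose as a group. Of its 23 measured genes all had higher means at hypertensive pressure, with a median log2 difference of 1.71 (camera, adjusted p = 1.26e-13, and adjusted p = 0.679 with an estimated correlation). Adjusted over the list alone, 17 genes passed, against 0 over all genes. Counts over a list alone are not adjusted across lists and are not separate support for a camera call. In this way 65 genes passed in 18 of the 36 lists tested. Lists that camera did not call also held such genes, with 4 of 7 for leukocyte adhesion molecules. The interferon list median was 3.20, 0.76 and 1.61 on hypertensive replicates 1, 2 and 3 and between -0.33 and 0.36 on the normotensive arrays. IFIT2 was at 7.20 times the normotensive signal (log2 2.85, SE 0.60), and at 4.33 times without hypertensive replicate 1 and 11.1 times without replicate 2. Of further members, the antiviral GTPase MX1 was at 2.93 times and IFI44L at 2.18 times. The antigen presentation list rose, with 15 of 17 genes higher (adjusted p = 0.000415, and adjusted p = 0.679 with an estimated correlation), and adjusted over the list alone 3 passed. The list median on hypertensive replicate 1, 0.43, lay below that on normotensive replicate 2, 0.45. Its members included TAPBP, the chaperone of peptide loading, at 3.44 times. The class I genes SLA-3 and SLA-2 had log2 differences of 0.99 and 1.42, which are uncertain because class I genes are near-identical in sequence. All 31 proteasome genes had higher means, with a median of 0.52 (adjusted p = 3.77e-08, and adjusted p = 0.702 with an estimated correlation), and adjusted over the list alone 0 passed. The estimated correlation between these genes was 0.656. The list median was 1.00 and 0.54 on hypertensive replicates 1 and 3 but 0.02 on replicate 2, inside the normotensive range of -0.14 to 0.11, and the groups did not overlap in 7 genes. PSME2, a subunit of the activator that interferon induces, was at 2.36 times, and the core subunit PSMA6 at 1.78 times.

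The list of inflammatory cytokines and chemokines rose, with 16 of 18 genes higher and a median log2 difference of 2.42 (adjusted p = 3.31e-10, and adjusted p = 0.679 with an estimated correlation). Adjusted over the list alone, 14 passed. The monocyte chemokines CCL2 and CCL8 were at 5.46 and 6.28 times the normotensive signal. IL6 and IL1B, chosen after their values were seen, were at 38.9 and 7.80 times, with log2 differences of 5.28 (SE 1.34) and 2.96 (SE 0.96). Their signals on hypertensive replicates 1, 2 and 3 were 22566, 297 and 2104 for IL6 and 8695, 524 and 612 for IL1B. The normotensive signal of IL6, 62.1, lay near the filter level, so the size of its fold is uncertain. The folds of IL6 and IL1B were 12.7 and 3.14 without hypertensive replicate 1 and 111 and 12.8 without replicate 2, and that of IL1B was 11.8 without replicate 3. The NF-kB list rose, with 10 of 10 genes higher (adjusted p = 5.95e-05, and adjusted p = 0.679 with an estimated correlation), and adjusted over the list alone 3 passed. CFLAR, an inhibitor of death-receptor signalling, was at 3.31 times and TNIP1 at 3.36 times. The immediate-early list rose, with 13 of 19 genes higher (adjusted p = 0.0211, and adjusted p = 0.702 with an estimated correlation), and adjusted over the list alone 1 passed. The transcription factor CEBPB was at 2.36 times and the phosphatase DUSP1 at 2.44 times. The list median on hypertensive replicate 3, -0.04, lay inside the normotensive range of -0.17 to 0.14. The immediate-early call was lost with array weights and without normotensive replicate 2 or hypertensive replicate 2.

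Markers of macrophages and other leukocytes did not pass, with 5 of 14 higher and a median log2 difference of -0.77 (adjusted p = 0.653). PTPRC, the pan-leukocyte CD45 gene, was at 77.6 under normotensive and 31.0 under hypertensive pressure. The hypertensive value of PTPRC lay below the filter level, so the size of its change is uncertain. The macrophage scavenger receptor CD163 was at 1636 and 751, although the CD163 groups overlapped and a further CD163 probe set had the opposite sign. Markers of endothelial cells did not pass (adjusted p = 0.920), with a median of -0.12 and a mean of 0.17, and with SELP, the P-selectin gene, at a log2 difference of 2.76 and ERG, an endothelial transcription factor, at -0.64. Cartilage markers did not pass either (adjusted p = 0.767). The marker lists of muscle, of blood and of adipocytes had 3, 4 and 2 measured genes, too few to be tested.

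The cell cycle list fell, with 23 of 25 genes lower and a median log2 difference of -0.73 (adjusted p = 7.75e-06, and adjusted p = 0.679 with an estimated correlation). Adjusted over the list alone, 6 passed. RRM2, a subunit of ribonucleotide reductase, was at 619 under normotensive and 84.0 under hypertensive pressure, topoisomerase TOP2A at 780 and 169, and cyclin CCNB1 at 714 and 177. The microtubule regulator STMN1 was at 5262 and 1999. The myofibroblast and contractile list fell, with 16 of 17 genes lower and a median of -0.52 (adjusted p = 0.0184, and adjusted p = 0.702 with an estimated correlation), and adjusted over the list alone 1 passed. The tropomyosins TPM1 and TPM2 had log2 differences of -1.49 (SE 0.30) and -1.28 (SE 0.37), and each had a further probe set with the opposite sign. The list median on hypertensive replicate 2, -0.15, lay at the low end of the normotensive range, which ended at 0.26. The call was lost with array weights.

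The list of matrix-degrading proteases and their inhibitors rose, with 13 of 20 genes higher (adjusted p = 0.00775, and adjusted p = 0.679 with an estimated correlation), and adjusted over the list alone 4 higher and 1 lower gene passed. Beside MMP3, the collagenase MMP1 was at 6.90 times the normotensive signal and ADAMTS1 at 4.67 times, while the metalloproteinase inhibitor TIMP1 was at 1.99 times. The inhibitors TIMP2 and TIMP3, chosen after their values were seen, had log2 differences of -0.56 (SE 0.19) and -1.26 (SE 0.39), and a further TIMP2 probe set had the opposite sign. TIMP3 was the lower gene that passed over the list alone. The call was lost with array weights. The list of elastic fibre, proteoglycan and glycoprotein matrix did not pass camera, with 15 of 22 genes lower (adjusted p = 0.245), and passed fry, which asks whether the genes shift one way on balance (adjusted p = 0.0339). Lumican (LUM) was at 13221 under normotensive and 7286 under hypertensive pressure, periostin (POSTN) at 14266 and 9858, and NID2 at 3087 and 1946. Fibrillar and basement membrane collagens did not pass (adjusted p = 0.487), with COL5A1 at a log2 difference of -1.23 (SE 0.35).

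The glycolysis list fell, with 12 of 16 genes lower and a median log2 difference of -0.69 (adjusted p = 0.0283, and adjusted p = 0.921 with an estimated correlation), and adjusted over the list alone 0 passed. The list median was -0.73 on hypertensive replicate 1 and -1.25 on replicate 3, and 0.10 on replicate 2, so the group means join arrays that differ. GPI and PFKM, enzymes of the upper pathway, had log2 differences of -1.69 (SE 0.55) and -1.25 (SE 0.45), and ENO2 and ALDOC were at -2.38 and -1.94. The call was lost without hypertensive replicate 3, alone or with normotensive replicate 3. The list of cholesterol and fatty acid synthesis rose, with 12 of 15 genes higher (adjusted p = 0.0324, and adjusted p = 0.865 with an estimated correlation), and adjusted over the list alone 1 passed. Its median was 1.02 and 0.51 on hypertensive replicates 1 and 3 but -0.27 on replicate 2, below the normotensive arrays at 0.0074 to 0.12. The cholesterol exporter ABCA1, the 1 gene that passed over the list alone, was at 2.37 times the normotensive signal. INSIG1 was at 1.95 times, with overlapping groups. Neither is an enzyme of synthesis, and no synthesis enzyme passed over the list alone. The call on this list was lost without normotensive replicate 1, hypertensive replicate 1 or hypertensive replicate 3, without replicate 3 of both groups, with the 60th percentile filter and with the mean of all probe sets.

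**Figure D3:**
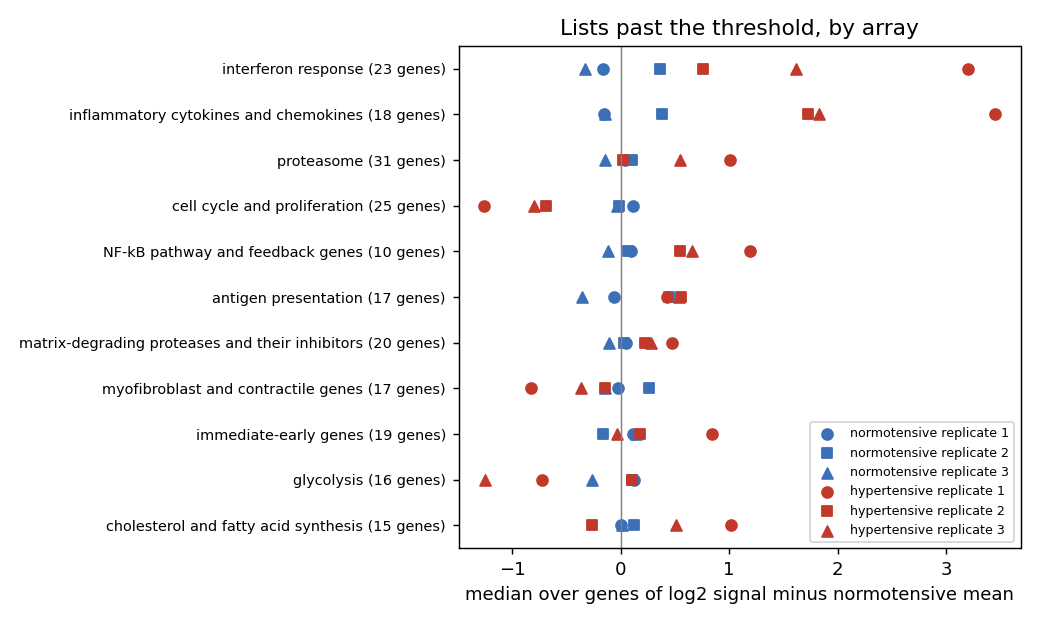
Median over the genes of each list past the camera threshold of the log2 signal minus the mean of the normotensive arrays, with 1 row per list and 1 point per array. The cytokine list lies at 3.45, 1.72 and 1.83 on hypertensive replicates 1, 2 and 3 and between -0.16 and 0.38 on the normotensive arrays.

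Of 36 lists tested, 11 passed camera, 8 higher and 3 lower, while 0 passed with an estimated correlation. For the 11, the estimated correlation ran from 0.055 to 0.784, all above the preset 0.01. Fry called 1, that of elastic fibre, proteoglycan and glycoprotein matrix, which was not among the 11, and 0 of the 11 passed fry. The 14 lists not described, among them those of TGF-beta, Wnt and MAPK signalling, integrins and heat shock, did not pass, with adjusted p from 0.146 to 0.984; that of leukocyte adhesion molecules passed, higher, without normotensive replicate 2 (adjusted p = 0.0458). The ratio of the 3′ to the 5′ control probe set of GAPDH was 3.02, 2.11 and 7.52 on normotensive replicates 1, 2 and 3 and 3.67, 2.91 and 6.04 on the hypertensive ones. Such ratios are read as a sign of RNA integrity, but here they were measured after repeated amplification and may reflect that too. The ratio of actin was 49.1, 41.1 and 109 on the normotensive arrays and 79.5, 81.7 and 52.5 on the hypertensive arrays, and that of EF1A 1.30 to 1.65 on the normotensive arrays and 1.55, 1.35 and 1.43 on the hypertensive arrays. Normotensive replicate 3 was highest of its group in all 3 ratios, while in the hypertensive group replicate 3 was highest for GAPDH and lowest for actin. GAPDH itself had a log2 difference of 0.11 (SE 0.15) that turned to -0.05 with quantile normalization, and ACTB one of 0.32 (SE 0.24).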

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

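The tests of replicate 2, of RNA degradation, of leukocytes and of scaling were chosen only after the patterns were seen; for RNA degradation, in place of an earlier test that rested on 1 array, and for the lists on which replicate 2 was compared, the limits were set with the values already known. Control probe sets of pig genes, which entered no comparison, were read for signals that lay above the normotensive arrays on all 3 hypertensive arrays and whose mean was at least 2 times theirs. The probe sets for the 3′ and middle part of RSAD2, an interferon-induced antiviral gene, did so, at 6.19 and 3.68 times the normotensive signal. These folds were 3.25 and 2.15 without hypertensive replicate 1, and the first was 9.87 without replicate 2. A probe set for the 5′ part of RSAD2 also lay above on all 3 hypertensive arrays, but at 1.54 times, under the limit. A probe set for 28S ribosomal RNA was at 2.19 times, while a further 28S probe set was at 1.23 times with overlapping groups, the 18S probe sets at 0.609 and 1.06 times and 5S at 1.01 times.

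Hypertensive replicate 2 lay nearer to the normotensive arrays than the other hypertensive arrays did, and had the lowest GAPDH 3′ to 5′ ratio of the hypertensive arrays. RNA degradation as the whole cause was not decided. The 3′ to 5′ ratios may also reflect the amplification of the RNA. Hypertensive replicates 1 and 3 lay inside the normotensive range of the GAPDH, actin and EF1A ratios. They correlated at no more than 0.904 with a normotensive array, where the lowest correlation between normotensive arrays was 0.952. The upper end of all 3 ranges was normotensive replicate 3 alone, at 7.52, 109 and 1.65, so this test also rests on 1 array. Hypertensive replicate 1 exceeded normotensive replicates 1 and 2 in all 3 ratios, at 3.67, 79.5 and 1.55. On a mislabelled normotensive array, 8 lists that parted replicates 1 and 3 from the other 4 arrays were read. In 4 of them, those of interferon, cytokines, NF-kB and the cell cycle, replicate 2 lay past the normotensive arrays toward replicates 1 and 3 by more than their SD. Medians, relative to the mean of replicate 2 and the normotensive arrays, were 1.29 against -0.45 to 0.07 for cytokines and -0.51 against 0.11 to 0.18 for the cell cycle. Set the same way, normotensive arrays did so in 0, 0 and 2 lists. Replicate 2 did not in the lists of proteasome, cholesterol synthesis, glycolysis and hypoxia. The limits were set with the medians known, and the 4 lists may not vary independently. With 4 arrays, few for such a bound, no conclusion is drawn from these counts. A test of probe sets did not decide: among probe sets that differed by at least 1 on the log2 scale between 1 normotensive array and both replicates 1 and 3, replicate 2 lay on the hypertensive side of another normotensive array in 48.9% to 64.6%, and normotensive arrays in 40.1% to 59.9%. Of 41 interferon and cytokine genes replicate 2 lay above all 3 normotensive arrays in 87.8% (25% by chance), and normotensive replicates 1, 2 and 3 above the other normotensive arrays in 14.6%, 73.2% and 12.2% (33.3% by chance), which is given as values only, since a first limit of 73.2% was raised, after the value was seen, to 107.7%, which no share can pass; a sample that responded in part stays open, untested.

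The interferon and cytokine lists were higher at hypertensive pressure. A larger share of leukocytes was taken to raise their markers by about as much, an assumption that was not tested. The median of 12 leukocyte markers on no other list was -0.47 (SD over genes 0.78), below the interferon median of 1.71. Of the leukocyte markers, PTPRC, CD14 and CORO1A had normotensive signals near the filter level. Their normotensive and hypertensive signals were 77.6 and 31.0, 40.7 and 73.8, and 71.4 and 123. Such signals show a change in share poorly, so the test does not decide on leukocytes. The abundant marker CD163, at 1636 under normotensive and 751 under hypertensive pressure, decides nothing alone, since hypertensive replicate 2 was at 1794, its fold was 1.31 without hypertensive replicate 1 and 3.36 without replicate 2, and a further probe set had a log2 difference of 0.80. Another scaling cannot decide on array scaling, since camera sets a list against all other genes and a shift common to all genes largely cancels. The higher adjusted p of both lists with quantile normalization or a median shift was 2.45e-09 at the preset correlation. With an estimated correlation the call is lost under the deposited scaling (adjusted p = 0.679 for each list). The median signed move of log2 differences was 0.042 with quantile normalization and 0.058 with the median shift, against list medians of 1.71 and 2.42. Moves of opposite sign cancel in such a median, so it does not give how far single genes moved. A response to pressure is a candidate explanation, as is any other difference between the samples, such as their donors, which the labels do not give.

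The 10 splits of the 6 arrays are too few for a share under 0.05. The real split gave 2436 probe sets at an unadjusted p under 0.05 and the highest other split 2088, and it was the only 1 of the 10 to reach its count. That other split exchanged hypertensive replicate 2 for normotensive replicate 3, and its count points to a structure of the samples in which replicate 2 sits with normotensive arrays. For probe sets past the threshold all 10 splits gave 0. For lists the real split gave 11 and the other splits 10, 10, 9, 9, 9, 8, 5, 2 and 1. The split of normotensive replicates 1 and 2 with hypertensive replicate 3 gave 9 lists. It gave 91 probe sets at an unadjusted p under 0.05, where chance gives 720. The count of lists called by camera at the preset correlation thus hardly sets the real split apart.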

How the results depend on the processing

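Leaving out replicate 3 of both groups was chosen after seeing the data; all other alternatives were planned. No probe set passed the threshold in the planned settings that kept all 6 arrays, except with array weights, which gave 5639 probe sets past it and 7030 at an unadjusted p under 0.05, against 0 and 2436. Over the settings without 1 array, the count past the threshold ran from 0 to 3513, and that at an unadjusted p under 0.05 from 1158 to 5676, both highest without hypertensive replicate 2. The latter count was 1395 without normotensive replicate 2, 1267 without normotensive replicate 3 and 1339 without hypertensive replicate 1, where fewer arrays enter the test. Without replicate 3 of both groups it was 801, with 0 past the threshold and 11 lists. The number of lists past the threshold, 11 as reported, was 0 with an estimated correlation and 10 to 13 in the other settings except fry. With fry it was 1, a list not among the 11. The robust variance model does not enter the list test and was not run for it. With the replicate block, 0 probe sets and 11 lists passed and 2865 probe sets had an unadjusted p under 0.05, so the block changed no count by over 1.5 times. Deviations of same-numbered arrays correlated at 0.06, 0.07 and 0.23, not all over the limit of 0.1, so the numbers were not used to pair the arrays. Every array nevertheless correlated best with its own number. The GAPDH 3′ to 5′ ratio was highest of its group on both replicate 3 arrays, at 7.52 and 6.04, though the actin ratio was not, at 109 and 52.5. A donor or batch shared by number stays open. Of 74 genes reported, 67 passed the threshold without hypertensive replicate 2 and 71 with array weights. Over all 14399 kept probe sets, 3513 and 5639 passed in these settings. Most of the 74 genes were named for a small p in the same data, so their higher share is no separate support. GAPDH turned to -0.053 with quantile normalization, -0.14 with array weights and -0.24 with the mean of all probe sets. The mean log2 difference of 5 lists with means near 0 turned. That of the ribosomal proteins turned from 0.017 to -0.11 with quantile normalization, -0.25 with array weights and -0.0094 with the mean of all probe sets, and ran from -0.094 to 0.15 without 1 array; the ribosomal list was called lower with quantile normalization and array weights (adjusted p = 0.0350 and 0.00511), and higher with a median shift, without replicate 3 of both groups and without hypertensive replicate 3 (adjusted p = 0.0458, 0.000102 and 2.23e-06). That of complement and coagulation turned from -0.0073 to 0.051 with a median shift, 0.21 with no filter, 0.033 with the 60th percentile filter, 0.11 and 0.087 with pseudocounts of 16 and 64, and 0.0056 with the mean of all probe sets, and ran from -0.33 to 0.32 without 1 array. The osteogenic list turned to 0.14 with no filter and 0.033 without replicate 3 of both groups, and ran from -0.36 to 0.0080 without 1 array. With array weights the endothelial and cartilage markers turned to -0.025 and -0.18, and the cartilage markers ran from -0.18 to 0.48 without 1 array. Of 14 further lists tested and not described, 9 turned in some setting, with 0 calls among the turned values. The cause of these changes was not tested. Probe sets near the filter level of 48.5 have the least signal over background.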

Other observations

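Several lists that did not pass held members with opposite signs. Of 26 genes of oxidative stress defence (adjusted p = 0.349), GCLM, a subunit of the enzyme that starts glutathione synthesis, was at 2.44 times the normotensive signal and glutathione reductase (GSR) at 2.26 times, while catalase (CAT) had a log2 difference of -1.10 (SE 0.40). Of 23 genes of complement and coagulation (adjusted p = 0.697), CFD was at 3.23 times and C5 at a log2 difference of -1.94 (SE 0.63). The hypertensive signal of C5, 46.6, lay below the filter level, so the size of its change is uncertain. The complement list had a median of 0.18 and a mean of -0.01. Matrix Gla protein (MGP), an inhibitor of calcification on the osteogenic list (adjusted p = 0.984, median 0.03 and mean -0.10), was at 10290 under normotensive and 5041 under hypertensive pressure. The hypoxia list (adjusted p = 0.176) had medians of -0.59, 0.18 and -0.95 on hypertensive replicates 1, 2 and 3, and passed, lower, with array weights and without hypertensive replicate 2 (adjusted p = 0.00570 and 0.0122); VEGFA had a log2 difference of -1.41 (SE 0.59). Mitochondrial oxidative phosphorylation genes had a median of -0.20 (adjusted p = 0.0738), and passed, lower, in 5 settings with adjusted p from 0.00620 to 0.0350: quantile normalization, no filter, and without normotensive replicate 3, hypertensive replicate 1 or replicate 3 of both groups. Of 56 ribosomal protein genes 0 had an unadjusted p under 0.05 (adjusted p = 0.299 for the list), and the list was called lower in 2 settings and higher in 3. With an estimated correlation the adjusted p of the hypoxia, mitochondrial and ribosomal lists was 0.921 each. None of these genes passed the genome-wide threshold.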
